A study of Danio rerio with 8 samples.

How the data were processed

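Gene expression was measured by RNA sequencing of cells sorted from the hearts of adult zebrafish (Danio rerio) aged 6 to 9 months. The fish carried a green fluorescent reporter driven by wt1b, a gene for a zinc finger transcription factor, and a red fluorescent reporter driven by the macrophage gene mpeg1. Hearts were injured by freezing part of the ventricle (cryoinjury) and cells were sorted by flow cytometry 4 days later. Per the labels' protocols, each of the 8 libraries came from a pool of 5 to 7 hearts, so the replicates of a population were taken as biological. The labels do not say whether libraries of equal number in the 2 populations share hearts. Polyadenylated RNA was amplified from 1 ng of total RNA, built into libraries in 2 batches and read from 1 end over 60 to 61 bases. Per the submitters' processing notes, CASAVA 1.8.2, cutadapt and RSEM 1.2.3 were used with the genome build Zv9. The role of each tool, the gene annotation and the gene filter are not given in the sources used here.

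The deposited values are a signal on a linear scale that the authors named normalized counts, with 1 column per library and 10479 Ensembl gene identifiers. Column totals lay between 803220 and 1021901, close to 1000000. How the authors normalized is not given in the sources used here. No value equals 0, the lowest is 0.0143, and low values follow no ladder of whole reads. On the log2 scale the mean of batch 1 minus the mean of batch 2 has a median over genes of -0.0006 and an SD of 0.659. These values bear the marks of an adjustment for library batch on a log scale, which no label states. If it moved each gene's mean by batch, the batch covariate used here takes up the degree of freedom it cost, and 5 residual degrees of freedom stand. If it also changed the spread or was fitted in another way, that cost is not counted, and the standard errors and adjusted p-values printed would be too small, which matters most for calls near 0.05. Read depth is therefore unknown, no counting interval can be given, and values under 1 may be products of the normalization rather than reads. In 10 sets, 48 identifiers in all hold identical values in all 8 libraries, and no gene named in the report is among them.

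Gene symbols were taken from a table of identifiers and symbols, which matched 8512 identifiers (81.2%). The 1967 unmatched identifiers hold 26.1% of the summed values. Many symbols are written in capitals after the human gene, and 332 symbols are shared by 673 identifiers, mostly paralogs. A shared symbol is printed with its identifier. How the authors assigned reads that fit several paralogs is not stated, so values of near-identical copies are uncertain. No genome sequence or annotation of the authors' build was used here, and no coordinates are printed.

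Samples were grouped by the fluorescence phenotype in the labels into 4 mCherry single positive and 4 eGFP/mCherry double positive libraries, with replicate numbers 1 and 2 in batch 1 and 4 and 5 in batch 2. Genes at 1 or more per 1000000 of the column total in at least 4 of 8 libraries were tested, 10127 in all, and 352 were left out. Values were taken to log2(value + 1) without further scaling. The test was the moderated test of limma 3.58.1 in R 4.3.3 with a mean-variance trend and library batch as a covariate, two-sided, called at a Benjamini-Hochberg adjusted p under 0.05. A fold change is on the log2(value + 1) scale, which understates the change of genes with low values. Standard errors are from the same fit.

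Before the data were examined, 24 gene lists were written from general knowledge. Lists with at least 5 tested members, 23 in all, were tested with camera in limma at a preset inter-gene correlation of 0.01, and again with an estimated correlation. A list symbol was matched regardless of case, or to the capital symbol without its paralog letter. The genes named in the text follow a rule fixed at the same time. It takes the reporter driver genes, and the 12 largest increases and 12 largest decreases among calls with 1 sign in both batches, a mean of at least 10 in the higher group and a characterised symbol. It adds up to 4 members of each list with the smallest p. Further genes are named where few members of a list were called, and in the closing section, and these were chosen after their values were seen. Some genes that the rule takes are not reported here, though they stay in the tests and counts of genes and lists.

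The fitting code was tested on simulated values for the 10127 genes of this comparison, with 50 genes changed by each of 4 fold sizes. It recovered 2% of the 2-fold, 16% of the 4-fold, 38% of the 8-fold and 78% of the 32-fold changes. Among its 70 calls 3 were false, and with no simulated change it made 0 calls. The genes changed by these folds were drawn from those above a minimum mean, so recovery of low genes was not tested. A simulated list of 40 shifted genes gave a camera p of 9.94e-14 and an unshifted one 0.634. The simulated genes varied independently, so this check could not test camera where list members are correlated. The estimated correlation of the macrophage list, for example, was 0.267. Changes of 2-fold were thus rarely detected in this simulation, in which 200 genes changed. The real comparison called 678 genes, so its cutoff on the unadjusted p was less strict and this recovery does not carry over to it. Its calls reached down to an absolute log2 fold change of 0.572.

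The alternatives tried were other covariates, each batch alone, each library left out in turn, quantile normalization, median centring, other pseudocounts and filters, other variance settings, a 2-fold minimum and an estimated list correlation. Other splits of the 8 libraries into 4 and 4 were fitted in the same way, but the split along the batches was fitted without the batch covariate. Gene list medians were compared by permutation of genes with 100000 resamples. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.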

Results

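RNA was sequenced from macrophage reporter cells of the cryoinjured adult zebrafish heart, sorted 4 days after injury into mCherry single positive cells and eGFP/mCherry double positive cells. Each population was represented by 4 libraries, and each library by a pool of 5 to 7 hearts. Library batches 1 and 2 each held 2 libraries of either population. The deposited normalized counts summed to between 803220 and 951137 in single positive and between 868929 and 1021901 in double positive libraries. The number of reads behind them is unknown. The share of genes with a value under 1 was 14.7% to 18.95% in single positive libraries and 10.7% to 19.7% in double positive libraries 2, 4 and 5. In double positive library 1 it was 42.3%. Across genes, the Pearson correlation of log2 values ran from 0.575 to 0.735 between libraries of the same population and from 0.466 to 0.641 between populations.

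The comparison asks how macrophages of the injured heart with wt1b reporter activity differ from those without it. The transcript of wt1b (ENSDARG00000007990), the gene that drives eGFP in the reporter line, checks the sort. Single positive libraries had 0.229 ± 0.165 normalized counts of wt1b (SD, n = 4) and double positive libraries 35.22 ± 21.9 (SD, n = 4). The values were 0.469, 0.203, 0.122 and 0.122 in single positive libraries 1, 2, 4 and 5, and 41.4, 13.6, 63.1 and 22.7 in double positive libraries 1, 2, 4 and 5. The log2 fold change was 4.67 (SE 1.12, limma adjusted p = 0.0177), with 4.23 in batch 1 and 5.12 in batch 2. Every double positive library lay above every single positive one. The call was lost without single positive library 2, 4 or 5 or double positive library 4 or 5 (adjusted p from 0.0507 to 0.0651), and in batch 1 alone (adjusted p = 0.341). The symbol MPEG1, of the pore-forming protein gene whose promoter drives mCherry, is carried by 3 identifiers. MPEG1 ENSDARG00000043093 rose from 30.3 ± 39.7 to 393 ± 171 (SD, n = 4 each), a log2 fold change of 4.33 (SE 0.65, adjusted p = 0.000734). MPEG1 ENSDARG00000055290 had 452 ± 103 in single and 352 ± 126 in double positive libraries (SD, n = 4 each, adjusted p = 0.497). The log2 fold change of MPEG1 ENSDARG00000078569 was 0.08 (adjusted p = 0.985).

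Macrophage, complement, lysosomal, lipid handling, neutrophil and chemokine genes lay higher in double positive cells. Tissue repair and extracellular matrix genes also passed as higher over both batches, but had medians of -0.20 and -2.03 in batch 1, and the latter list was lost without single positive library 4 or 5 or double positive library 4 or 5 (adjusted p from 0.187 to 0.407). Lymphocyte, endothelial, immediate early and ribosomal protein genes lay lower. These 8 and 4 lists of the 23 tested passed camera's threshold with its preset correlation, and 0 passed with an estimated correlation, where 4 had an unadjusted camera p under 0.05. By single genes, the populations differed in 678 of 10127 tested genes, of which 393 were higher and 285 lower in double positive cells (limma, adjusted p under 0.05). The change was at least 2-fold for 368 of the higher and 259 of the lower genes. All 678 had the same sign in both batches. A gene of opposite signs is unlikely to be called in a fit over both, so this is not replication. Every double positive library lay above every single positive library for 370 of the higher genes, and below for 266 of the lower genes. Over all tested genes, 14.1% showed such separation in either direction. Chance would give 2.86% if all splits of the 8 libraries into 4 and 4 were equally likely, which ignores the batches. The median log2 fold change of all tested genes was -0.16, and changes are to be read against it. It was 0.07 with median centring and -0.04 with quantile normalization, and with median centring the split was 492 higher and 225 lower. Leaving out 1 library moved the counts by more than 1.5 times in several cases. The higher and lower counts were 248 and 109 without single positive library 4, 259 and 127 without single positive library 5, 176 and 145 without double positive library 4, and 169 and 101 without double positive library 5. The lower count was 136 without single positive library 1 and also 136 without single positive library 2. Without any single library, 144 of the higher and 64 of the lower genes stayed past the threshold. Batch 2 alone gave 412 higher and 152 lower genes, while batch 1 alone gave 0 (limma, 1364 genes at an unadjusted p under 0.05). Without the mean-variance trend the counts were 124 and 195.

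The 12 genes of largest increase had means of 0.364 to 35.05 normalized counts in single positive cells. The integrin alpha E gene itgae.1 rose from 34 ± 61.4 to 592 ± 277 normalized counts (SD, n = 4 each), a log2 fold change of 6.31 (SE 1.04, adjusted p = 0.00123). The tetraspanin gene cd9b rose by 6.22 (SE 0.91), the guidance receptor gene robo4 by 5.95 (SE 0.79) and the scavenger receptor gene marco by 5.56 (SE 0.71) on the log2 scale. MFAP4 ENSDARG00000090783 reached 812 ± 426 in double positive cells from 35.05 ± 55.5 (SD, n = 4 each). The log2 fold changes of MFAP4 ENSDARG00000090557, SLC45A3, havcr1, DOCK4 ENSDARG00000076213, MOXD1, FN1 ENSDARG00000006526 and SLC2A6 lay between 4.99 and 5.48. Of these 12 genes, MOXD1 alone lost its call when 1 library was left out (adjusted p = 0.0652 without double positive library 5). Single positive library 1 held the highest single positive value of 8 of the 12, such as 126 for itgae.1 against 0.174 to 9.60 in the other single positive libraries.

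The 12 genes of largest decrease had means of 54.8 to 357 normalized counts in single positive and 0.201 to 5.22 in double positive cells. The highest double positive values were 16.2 of cnksr1 and 9.54 of SPOCK3, both in double positive library 1, whose median over genes was 7.21. The tetraspanin gene cd37, expressed in B lymphocytes, had 158 ± 97.8 in single and 0.285 ± 0.077 in double positive libraries (SD, n = 4 each), a log2 fold change of -6.73 (SE 0.97, adjusted p = 0.000544). The chemokine receptor CXCR4 ENSDARG00000057633 fell by 6.58 (SE 0.95) on the log2 scale, the immunoglobulin heavy chain gene ighm by 6.33 (SE 0.98) and irf4b, which encodes an interferon regulatory factor of lymphoid cells, by 6.31 (SE 0.93). The matrix proteoglycan gene SPOCK3 had the smallest p of all tested genes. It fell from 357 ± 50.6 to 4.50 ± 3.60 (SD, n = 4 each), a log2 fold change of -6.23 (SE 0.57, adjusted p = 3.28e-05). The log2 fold changes of SYNGR3, cnksr1, stk17al, RBM38, ANK3, ppt2a.2 and plaat1l lay between -5.99 and -5.42. Each of these 12 genes stayed past the threshold without any single library.

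**Figure D1:**
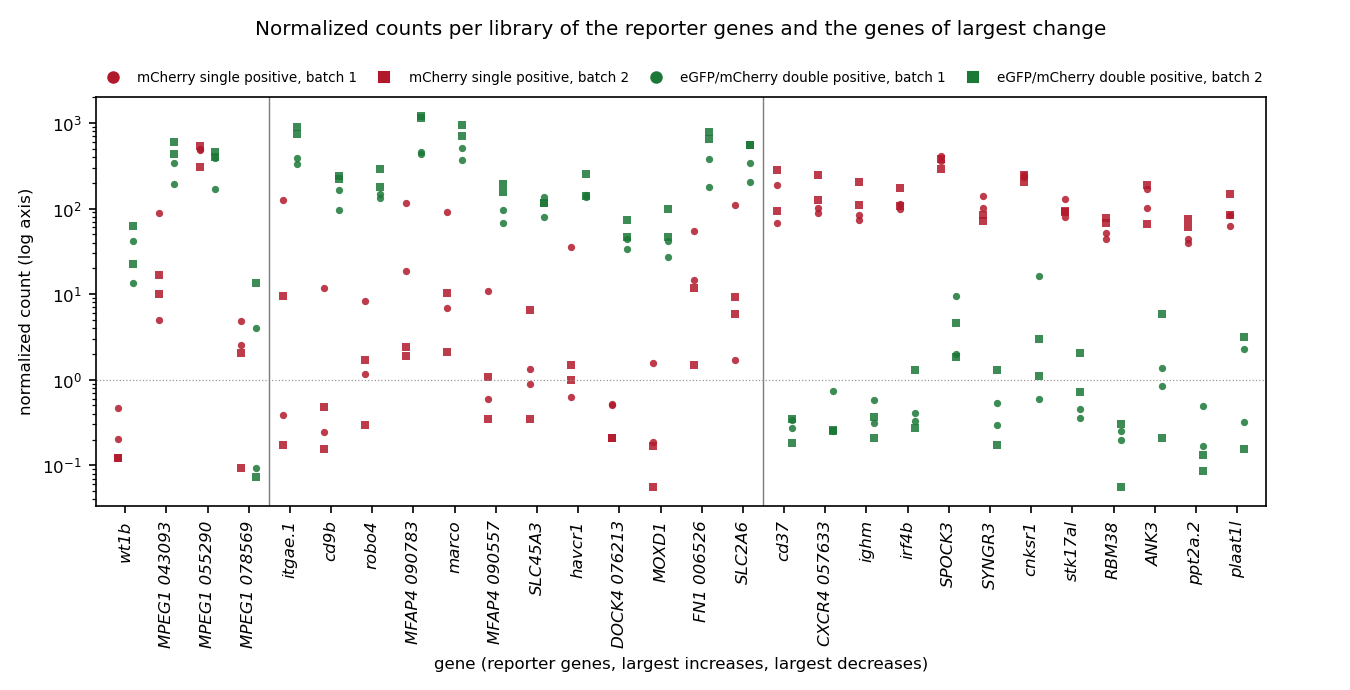
Normalized counts per library on a log axis for the reporter genes, the 12 genes of largest increase and the 12 of largest decrease, with single positive libraries in red, double positive libraries in green, batch 1 as circles and batch 2 as squares. The dotted line marks a value of 1, and wt1b lies at 0.122 to 0.469 in single positive and at 13.6 to 63.1 in double positive libraries.

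Macrophage markers lay higher as a list in double positive cells, but its members differed. Of 34 tested members 18 rose and 1 fell, or 22 and 3 adjusted over the list alone, and the median log2 fold change was 2.12. Besides marco, MPEG1 ENSDARG00000043093 and 5 MFAP4 identifiers of an extracellular glycoprotein family, the mannose receptor gene mrc1b rose from 123 ± 103 to 715 ± 217 (SD, n = 4 each, log2 fold change 2.90, SE 0.43). MFAP4 ENSDARG00000038681 lost its call without double positive library 5 (adjusted p = 0.0511) and MFAP4 ENSDARG00000038683 without any of 6 libraries (all but double positive 1 and 2, adjusted p up to 0.0868). The member that fell was IRF8, a transcription factor gene of macrophage development, with a log2 fold change of -2.93 (adjusted p = 0.0432). IRF8 lost its call without any of 6 libraries (single positive 1, 2, 4 or 5, double positive 4 or 5), with an adjusted p of up to 0.165. The receptor gene csf1rb (log2 fold change -1.23) and the antigen presentation gene cd74a (-0.47) fell when adjusted over the list alone. Other abundant members did not pass, among them cd68 with 551 and 787 normalized counts in single and double positive cells, SPI1 with 461 and 554, and CORO1A with 294 and 279. The list lay above the other genes by camera (adjusted p = 5.70e-16), but adjusted p = 0.237 with an estimated correlation. Its median was 1.58 in batch 1 and 2.26 in batch 2. In the same comparison the medians of lymphocyte and endothelial markers were -2.59 and -2.26. Complement genes, which overlap this list in the 3 C1q genes, had a median of 3.66, with 5 of 11 members higher and 0 lower (6 and 0 adjusted over the list alone). The risen genes were the properdin gene cfp, from 161 ± 141 to 1433 ± 380 (SD, n = 4 each), and c1qa, c1qb, c1qc and c7b, at log2 fold changes of 3.86 to 4.72. This list also passed (camera adjusted p = 7.10e-06), but had adjusted p = 0.270 with an estimated correlation, with medians of 1.94 and 4.69 in batches 1 and 2.

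Lysosomal and lipid handling genes were also higher. Among 44 genes of lysosome and phagocytosis 16 rose and 1 fell (23 and 1 adjusted over the list alone), and the median log2 fold change was 0.92. The aspartic protease gene CTSD rose from 156 ± 116 to 837 ± 164 (SD, n = 4 each), a log2 fold change of 2.89 (SE 0.46, adjusted p = 0.00116). The proton pump subunit gene ATP6V0C rose by 1.17 (SE 0.19), the granulin gene grnas by 1.71 (SE 0.32) and the lysosomal channel gene MCOLN1 by 2.29 (SE 0.44) on the log2 scale. The sialidase gene NEU1 was the member that fell (-1.55, adjusted p = 0.0298, lost without any of 7 libraries, all but double positive library 1, adjusted p up to 0.0963). The list passed at a camera adjusted p = 1.54e-13, with adjusted p = 0.237 with an estimated correlation, with medians of 0.67 in batch 1 and 1.31 in batch 2. Of 34 lipid and cholesterol handling genes 8 rose and 0 fell (9 and 1 adjusted over the list alone), with a median of 0.76. The cholesterol exporter gene abca1b rose from 396 ± 170 to 1040 ± 211 (SD, n = 4 each, log2 fold change 1.49, SE 0.30). The apolipoprotein gene apoeb rose by 4.88 (SE 1.06), a call lost without double positive library 4 (adjusted p = 0.1003) or 5 (adjusted p = 0.0606). This list passed at a camera adjusted p = 0.000121, with adjusted p = 0.270 with an estimated correlation, and the batch medians were 0.57 and 1.35.

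Genes of chemokine signalling and migration changed in both directions. Of 51 tested members 10 rose and 4 fell (14 and 6 adjusted over the list alone), and the median log2 fold change was 0.37. The chemokine receptor gene cxcr3.3 rose from 9.99 ± 9.58 to 227 ± 105 (SD, n = 4 each, log2 fold change 4.83, SE 0.74) and the chemerin receptor gene CMKLR1 by 2.35 (SE 0.37). The chemokine receptor genes CXCR4 ENSDARG00000057633 and CCR9 fell, CCR9 from 550 ± 231 to 91.7 ± 48.1 (SD, n = 4 each). Camera gave adjusted p = 0.00351 for the list and adjusted p = 0.419 with an estimated correlation, with batch medians of 0.16 and 0.86. The median ran from 0.15 without single positive library 4 to 0.70 without single positive library 1. In the list of alternative activation and tissue repair, 6 of 29 members rose and 2 fell (6 and 3 adjusted over the list alone). Those that rose included mrc1b, FN1 ENSDARG00000006526 and marco, which rose from 27.9 ± 43.1 to 631 ± 249 (SD, n = 4 each). The fallen members were the arginase gene ARG2 (-1.97, lost without single positive library 2 or 4 or double positive library 5, adjusted p up to 0.0725) and the receptor gene TGFBR2 ENSDARG00000034541 (-4.76, lost without single positive library 4 or double positive library 4 or 5, adjusted p up to 0.0846). The list median was 0.78 (camera adjusted p = 0.0111, adjusted p = 0.437 with an estimated correlation), but -0.20 in batch 1 (adjusted p = 0.366 in batch 1 alone) and 1.55 in batch 2, and ran from 0.31 without double positive library 4 to 1.13 without single positive library 1.

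The proinflammatory list did not pass the threshold as a group (camera adjusted p = 0.0910, adjusted p = 0.793 with an estimated correlation, batch medians 0.07 and 0.74). It passed with median centring (adjusted p = 0.0167), in batch 2 alone (adjusted p = 0.00998), without single positive library 2 (adjusted p = 0.0412) and without double positive library 5 (adjusted p = 0.0422). Its 22 members included 3 that rose and 2 that fell (6 and 3 adjusted over the list alone). ACOD1, the gene for the enzyme that makes itaconate, rose from 66.2 ± 52.3 to 1335 ± 575 (SD, n = 4 each, log2 fold change 4.87, SE 0.63, adjusted p = 0.000280). The cytokine gene tnfa rose from 57.1 ± 24.4 to 178 ± 79.2 (SD, n = 4 each), but its adjusted p of 0.0402 passed 0.05 without any of 6 libraries (all but single positive library 2 and double positive library 1, adjusted p from 0.0738 to 0.198). The prostaglandin synthase gene PTGS2 ENSDARG00000010276 fell by 3.32 on the log2 scale (SE 0.70), a call lost without single positive library 2 (adjusted p = 0.0535). The chemokine gene ccl34a.4 rose by 2.69 (adjusted p = 0.0409) and ccl35.2 fell by 1.00 (adjusted p = 0.0341). The first was lost without any of 5 libraries (single positive 2, 4 or 5, double positive 4 or 5, adjusted p up to 0.229) and the second without any of 6 (all but double positive libraries 2 and 4, adjusted p from 0.05001 to 0.116).

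Extracellular matrix genes had opposite directions in the batches. The median log2 fold change of 41 members was 0.48 over both batches, -2.03 in batch 1 and 2.45 in batch 2. The list passed the threshold (camera adjusted p = 0.0449, adjusted p = 0.802 with an estimated correlation). It did not pass without single positive library 4 or 5 or double positive library 4 or 5 (adjusted p from 0.187 to 0.407, medians from -0.24 to 0.16), while without double positive library 1 the median was 1.204 (adjusted p = 5.98e-05). Of its members 5 rose and 0 fell (6 and 0 adjusted over the list alone). The 5 had a log2 fold change above 0 in both batches, but that of FN1 ENSDARG00000019815 was 0.116 in batch 1 and 4.095 in batch 2. These were both fibronectin identifiers, the protease inhibitor gene TIMP2 ENSDARG00000075261, the proteoglycan gene vcanb and the membrane protease gene MMP14 ENSDARG00000008388. Fibronectin FN1 ENSDARG00000006526 rose from 20.4 ± 23.1 to 497 ± 270 and vcanb from 33.5 ± 49.3 to 426 ± 156 (SD, n = 4 each). MMP14 lost its call without double positive library 4 (adjusted p = 0.0525) or 5 (adjusted p = 0.0694), and FN1 ENSDARG00000019815 without single positive library 4 or 5 or double positive library 4 or 5 (adjusted p up to 0.182).

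Markers of other cell types moved in different directions. Lymphocyte and NK markers were lower in double positive cells, with 6 of 11 members lower and 0 higher (6 lower and 1 higher adjusted over the list alone) and a median log2 fold change of -2.59. Besides ighm and CCR9, the B lymphocyte transcription factor gene PAX5 fell from 50.9 ± 27.9 to 0.172 ± 0.060 (SD, n = 4 each, log2 fold change -5.35, SE 1.11). The immunoglobulin gene ighd fell by 4.87 (SE 0.93), a call lost without single positive library 4 (adjusted p = 0.0516). The member higher when adjusted over the list alone was the B lymphocyte marker cd22, with 2.03 ± 2.30 in single and 33.5 ± 16.4 in double positive libraries (SD, n = 4 each, log2 fold change 3.65, limma adjusted p = 0.0706 over all genes). The lymphocyte list passed at a camera adjusted p = 0.00185, with adjusted p = 0.237 with an estimated correlation, and batch medians were -2.01 and -3.55. Among 20 endothelial and endocardial markers 4 fell and 1 rose (10 and 2 adjusted over the list alone), with a median of -2.26 and batch medians of -2.78 and -1.83 (camera adjusted p = 1.58e-05, adjusted p = 0.243 with an estimated correlation). Those that fell were SPOCK3, the flow-responsive gene klf2b, from 279 ± 63.7 to 35.7 ± 18.6 (SD, n = 4 each), the von Willebrand factor gene vwf and NOTCH1, and robo4 rose. Leaving out 1 library ended the calls of vwf (any single positive library or double positive library 5, adjusted p from 0.0573 to 0.0850) and NOTCH1 (single positive library 2 or 5 or double positive library 5, adjusted p from 0.0781 to 0.0904).

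Of the neutrophil markers, 3 of 11 rose and 0 fell (4 and 1 adjusted over the list alone), with a median of 0.77. The 3 were adam8a, the oxidase subunit gene NCF1 and the receptor gene CSF3R, all of which macrophages can also express. NCF1 rose from 718 ± 75.2 to 1480 ± 412 (SD, n = 4 each, log2 fold change 1.01, SE 0.21). CSF3R lost its call without double positive library 4 (adjusted p = 0.0790) or 5 (adjusted p = 0.112). Camera gave adjusted p = 0.00351 for the list, adjusted p = 0.270 with an estimated correlation and adjusted p = 0.0713 in batch 2 alone, with batch medians of 1.104 and 1.11. Epicardial and fibroblast markers did not pass (13 members, median 0.26, camera adjusted p = 0.259, adjusted p = 0.802 with an estimated correlation). Their median was -1.51 in batch 1 and 2.43 in batch 2, where the list passed alone (adjusted p = 0.00326). It was 1.12 without double positive library 1 (adjusted p = 0.0846) and, over each library left out in turn, ran from -0.49 to 1.30. Of the members, wt1b and the smooth muscle gene TAGLN rose (3 rose and 1 fell adjusted over the list alone), and TAGLN lost its call without any of 5 libraries (single positive 1, 4 or 5, double positive 4 or 5, adjusted p from 0.0573 to 0.153). Cardiomyocyte markers had a median of -0.23 over 17 members (camera adjusted p = 0.482, adjusted p = 0.871 with an estimated correlation). It was -3.03 in batch 1, where the list passed alone (adjusted p = 0.00558), and 1.54 in batch 2. Without double positive library 1 it was 0.12 with camera's direction still downward (adjusted p = 0.769), and over the libraries left out in turn it ran from -0.82 to 0.15. The myoglobin gene mb was the 1 member called, also adjusted over the list alone, and fell from 165 ± 75.2 to 16.5 ± 24.3 (SD, n = 4 each). It lost its call without single positive library 5 (adjusted p = 0.0505). Of 7 erythrocyte and thrombocyte markers, f13a1b, a coagulation factor XIII gene, rose from 30.2 ± 29.2 to 492 ± 109 (SD, n = 4 each, log2 fold change 4.39, SE 0.47, adjusted p = 9.14e-05). It was also the 1 called adjusted over the list alone, and the list did not pass (median 0.26, camera adjusted p = 0.185, adjusted p = 0.480 with an estimated correlation, batch medians 0.67 and 0.63, -0.16 without single positive library 1 and 0.88 without single positive library 2).

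**Figure D2:**
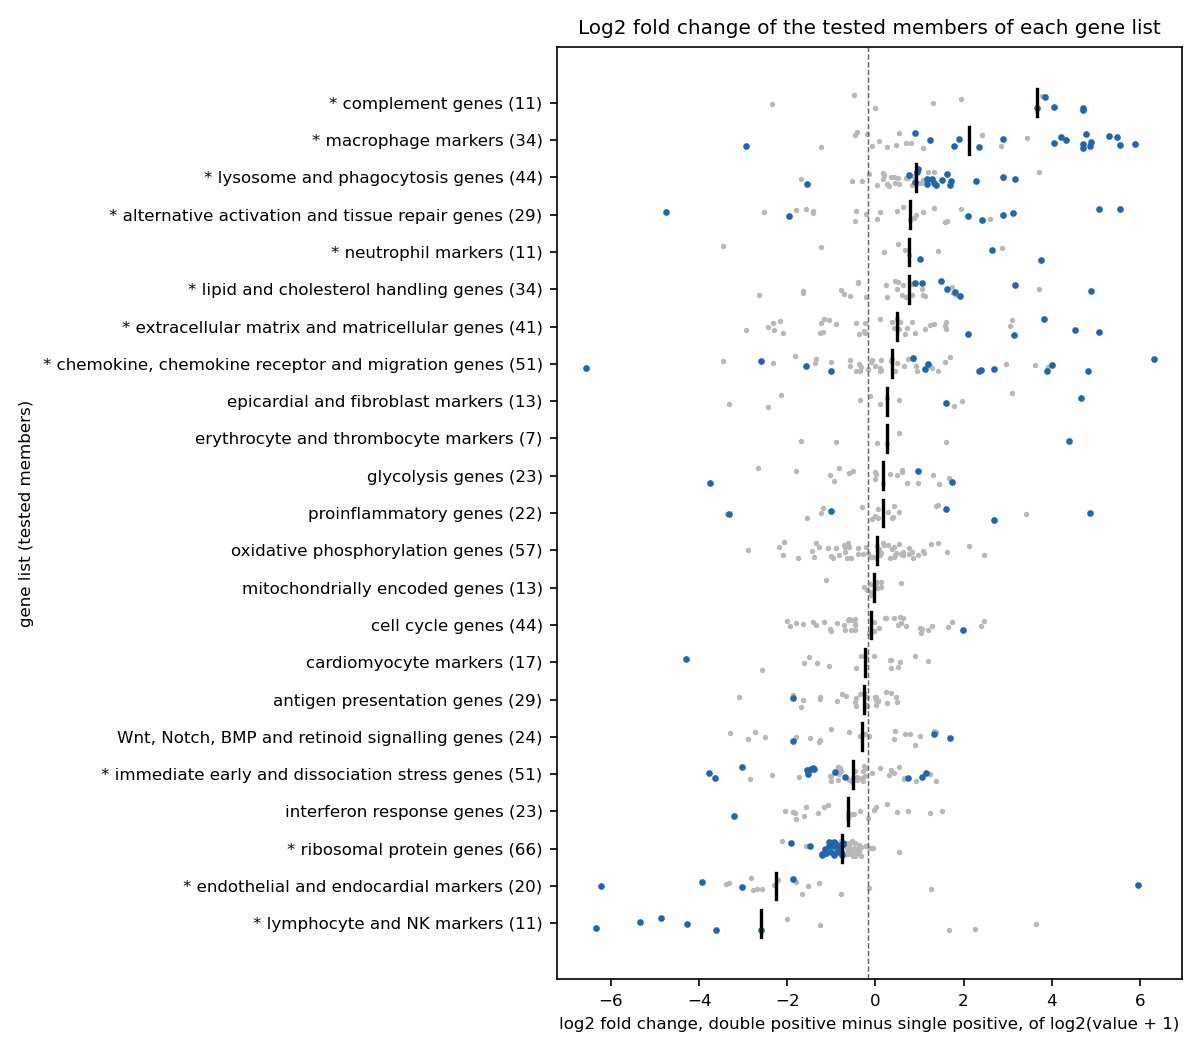
Log2 fold change (double positive minus single positive, on log2(value + 1)) of each tested member of the 23 gene lists, with members past the threshold in blue, others in grey, a black bar at each list's median and a dashed line at the median of all tested genes, -0.16. An asterisk marks the 12 lists past the camera threshold, from complement genes at a median of 3.66 to lymphocyte and NK markers at -2.59, and all 12 are lost with an estimated correlation.

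Immediate early and dissociation stress genes and ribosomal protein genes were lower in double positive cells. Of 51 immediate early and stress genes 10 fell and 3 rose (19 and 4 adjusted over the list alone), with a median log2 fold change of -0.51. The orphan receptor gene NR4A1 fell from 1048 ± 176 to 419 ± 189 and JUN from 508 ± 57.0 to 182 ± 72.5 (SD, n = 4 each). The log2 fold change of egr1 was -1.41 (SE 0.29, adjusted p = 0.00721). BTG1, maff and ZFP36L1 ENSDARG00000021443 rose, at log2 fold changes of 0.75, 1.05 and 1.14. The call of BTG1 held without any single library, while maff and ZFP36L1 lost theirs without any of 6 (all but double positive 1 and 2) and any of 5 libraries (single positive 2, 4 or 5, double positive 4 or 5), at an adjusted p of up to 0.138 and 0.153. With median centring 7 members fell and 4 rose, and with quantile normalization 15 fell and 2 rose. Camera gave adjusted p = 0.000220 and adjusted p = 0.271 with an estimated correlation, and batch medians were -0.64 and -0.43. Of 66 ribosomal protein genes 25 fell and 0 rose (44 and 0 adjusted over the list alone), and 1 of 66 had a log2 fold change above 0. The median was -0.75, with -0.57 in batch 1 and -0.90 in batch 2. RPS26 ENSDARG00000030408 fell from 410 ± 120 to 148 ± 48.2 and RPL27 from 809 ± 80.4 to 410 ± 140 (SD, n = 4 each). The ribosomal list passed at a camera adjusted p = 3.99e-20, with adjusted p = 0.270 with an estimated correlation. With median centring the list still passed (camera adjusted p = 1.65e-07). Its distance from the median of all genes stayed at -0.59, which is fixed because centring shifts all genes alike. Its median was -0.53 and 1 member fell, RPS26 ENSDARG00000030408, while RPL27 lost its call (log2 fold change -0.82, limma adjusted p = 0.165). With quantile normalization 35 members fell and 0 rose (camera adjusted p = 4.34e-27), RPL27 among them (limma adjusted p = 0.00118).

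Antigen presentation genes did not pass the threshold (29 members, median -0.27, batch medians -0.37 and -0.32, camera adjusted p = 0.110, adjusted p = 0.271 with an estimated correlation). They passed without double positive library 1 (adjusted p = 0.0497) and with quantile normalization (adjusted p = 0.0395). The 1 member called, also adjusted over the list alone, was cd83, a marker of mature antigen presenting cells, which fell from 1294 ± 354 to 353 ± 82.2 (SD, n = 4 each, log2 fold change -1.87, SE 0.24, adjusted p = 0.000280). Interferon response genes had a median of -0.62 over 23 members, -1.61 in batch 1 and 0.23 in batch 2 (camera adjusted p = 0.256, adjusted p = 0.871 with an estimated correlation, adjusted p = 0.0405 in batch 1 alone). Without double positive library 1 the median was 0.03 and camera's direction upward (adjusted p = 0.902). IRF7 was the 1 member called, also adjusted over the list alone, and lost its call without any of 6 libraries (all but double positive libraries 1 and 2, adjusted p from 0.0533 to 0.138).

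Genes of the cell cycle, energy metabolism and developmental signalling did not pass as groups. The median of 44 cell cycle genes was -0.10, with batch medians of -0.47 and 0.57 (camera adjusted p = 0.688, adjusted p = 0.898 with an estimated correlation), and camera's direction was upward. DNMT1, a DNA methyltransferase gene, rose from 16.9 ± 6.39 to 67.3 ± 11.14 (SD, n = 4 each), but lost its call without any of 7 libraries (all but double positive library 1, adjusted p from 0.0650 to 0.205), and 0 members were called adjusted over the list alone (limma, 3 at an unadjusted p under 0.05, all higher). Among 57 oxidative phosphorylation genes limma called 0, also adjusted over the list alone (3 at an unadjusted p under 0.05), and the median of 0.04, mean of -0.11 and upward direction of camera differed in sign (adjusted p = 0.735, adjusted p = 0.898 with an estimated correlation, batch medians -0.38 and 0.28). Glycolysis genes also differed in sign between the median of 0.17 and the mean of -0.05 (23 members, camera adjusted p = 0.271, adjusted p = 0.605 with an estimated correlation, batch medians 0.09 and 0.16). Of these, 2 rose and 1 fell (3 and 1 adjusted over the list alone). PFKFB3, a regulator of glycolytic flux, rose from 632 ± 237 to 2030 ± 455 (SD, n = 4 each, log2 fold change 1.75, SE 0.27). The glucose transporter genes slc2a3b and SLC2A1 had log2 fold changes of 0.97 and -3.75. Their calls were lost without single positive library 4 or 5 or double positive library 4 or 5 for slc2a3b (adjusted p from 0.0618 to 0.0997) and without any single positive library for SLC2A1 (adjusted p from 0.0502 to 0.0621). In the list of Wnt, Notch, BMP and retinoid signalling, notch2 rose from 419 ± 104 to 1040 ± 154 (SD, n = 4 each, log2 fold change 1.34, SE 0.22). RDH10 ENSDARG00000012369 also rose, a call lost without single positive library 5 or double positive library 4 or 5 (adjusted p from 0.0555 to 0.126), and NOTCH1 fell. These 2 increases and 1 decrease were also those adjusted over the list alone, and the list median was -0.30 over 24 members (camera adjusted p = 0.735, adjusted p = 0.898 with an estimated correlation, batch medians -1.20 and 1.04). The 13 mitochondrially encoded genes had a median of -0.03, with -0.74 in batch 1 and 0.75 in batch 2, and limma called 0 of them (1 at an unadjusted p under 0.05, the same 1 higher adjusted over the list alone). Camera gave adjusted p = 0.762 and adjusted p = 0.925 with an estimated correlation, with an upward direction against a median and mean (-0.08) below 0. Within batches the list passed in opposite directions at the preset correlation, against an estimated one of 0.785, with adjusted p = 3.89e-07 downward in batch 1 alone and adjusted p = 0.000288 upward in batch 2 alone. Without double positive library 1 the medians of the cell cycle, oxidative phosphorylation, signalling and mitochondrially encoded lists were 0.45, 0.34, 0.07 (camera's direction downward) and 0.24, and none passed.

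**Figure D3:**
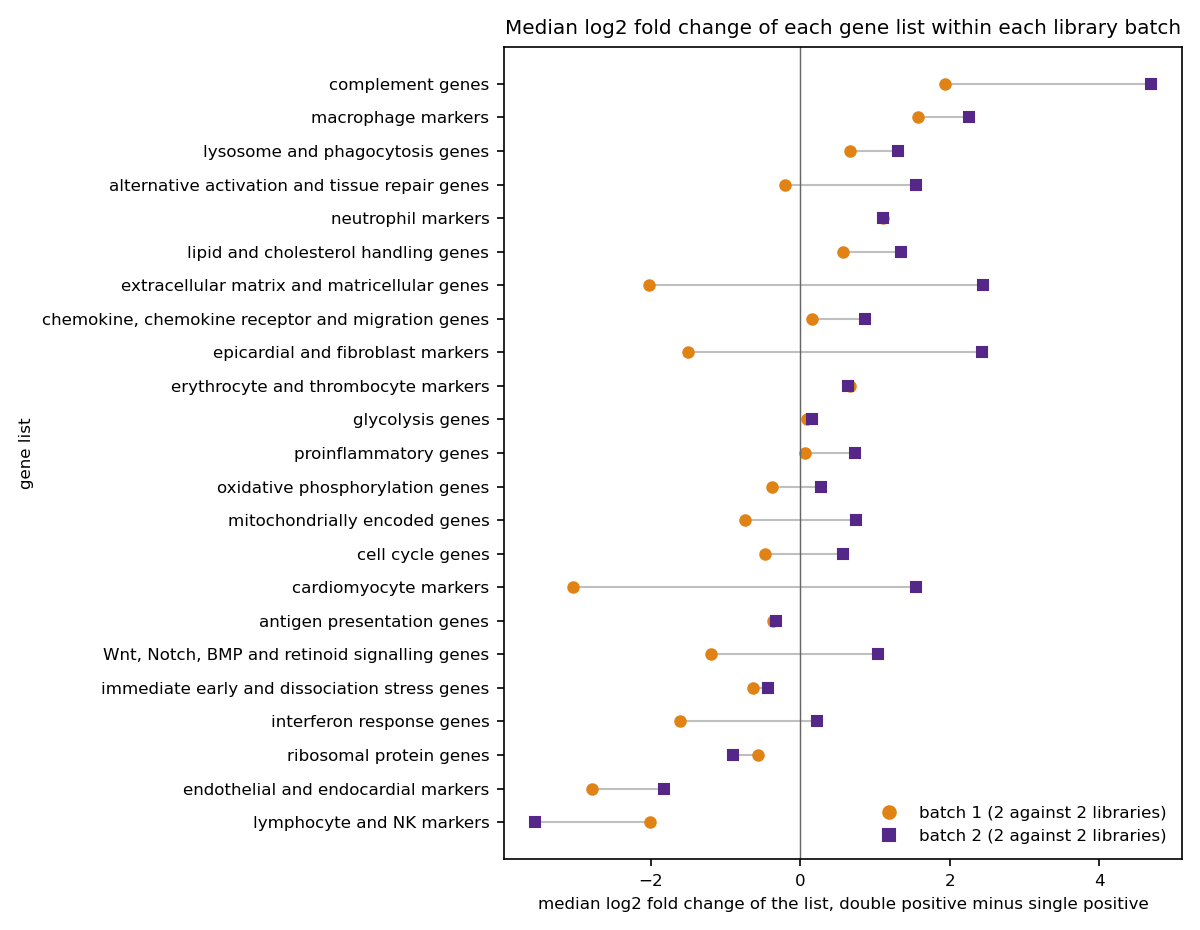
Median log2 fold change of each gene list (double positive minus single positive) within batch 1, as orange circles, and within batch 2, as purple squares, each from 2 against 2 libraries. The cardiomyocyte list lies at -3.03 and 1.54 and the extracellular matrix list at -2.03 and 2.45, while the macrophage list lies at 1.58 and 2.26.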

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

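The 2 tests of the B lymphocyte pattern, the spread test of batch 1 and the test of macrophage share as the whole cause were chosen after the results they bear on were seen, as was the reading of the neutrophil list. Of the 35 splits of the 8 libraries into 4 and 4, the real split called 678 genes and the highest of the others 1 gene. It was the 1 split with so many genes. Splits that do not take 2 libraries of each batch into each group mix the groups with batch, so the 35 together cannot exclude chance. In 18 of the 35 each group takes 2 libraries of each batch, and the highest of the others among these called 0 genes (limma, up to 895 at an unadjusted p under 0.05). A share of 1 in 18 is above 0.05, so these 18 cannot exclude chance either.

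Macrophage markers were higher in double positive cells, with a median log2 fold change of 2.12. The tables argue against the low complexity of double positive library 1 as the cause, since 19 of 34 members rose without it (camera adjusted p = 7.95e-16, and from 7.85e-20 to 2.34e-13 over the 8 libraries left out in turn, but adjusted p = 0.237 over all 8 libraries with an estimated correlation), and against library batch, since its excess over the median of all genes was at least 1.97 in each batch. A larger share of macrophages as the whole cause would raise all genes made by macrophages alone by 1 factor. Of 22 members with a mean of at least 100, the 95% interval of the change lay below the list median for 11 and above it for 7. The 11 cannot count against this cause, because all are also known from other cells, whose share could hide a change. They include cd68, SPI1, CORO1A, cd74a and MPEG1 ENSDARG00000055290 (452 in single and 352 in double positive cells). The last shares the name of the reporter both gates select for. The intervals of the 7, with c1qa lowest (2.61 to 5.49), lay above those of SLC7A7 (1.28 to 2.52) and lygl1 (1.18 to 2.39). This comparison was made after the values were seen. It argues against 1 factor for these genes, unless other cells also make SLC7A7 and lygl1, which was not tested. A larger share as part of the cause stays open. A purer double positive sort with fewer cells of every other type is not settled. It would put every other cell type list below the median of all genes, which was not met. Relative to that median, neutrophil markers lay at 0.93, epicardial and fibroblast markers at 0.419 and erythrocyte and thrombocyte markers at 0.416. Lymphocyte, endothelial and cardiomyocyte markers lay below it. The epicardial and erythrocyte lists were not called (camera adjusted p = 0.259 and 0.185). Neutrophil markers (median 0.771, camera adjusted p = 0.00351) met the bound written against this cause, another cell type list called higher. They cannot decide, because their 3 called genes, adam8a, NCF1 and CSF3R, can be expressed by macrophages. Their call too was lost with an estimated correlation (adjusted p = 0.270). A difference in state or kind between the macrophages of the gates, which the design compares, may account for the higher macrophage markers as well. It was not tested apart from purity.

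Of the genes taken here as B lymphocyte genes, cd37, ighm, irf4b, PAX5 and cd79a had means under 1 in double positive cells, while ighd had 25.1 in double positive library 1. The fall of cd79a, from 34.7 to 0.150 (limma adjusted p = 0.0357), lost its call without single positive library 1, 2 or 4 or double positive library 2, 4 or 5 (adjusted p up to 0.137). In the other direction, cd22 went from 2.03 to 33.5 with every double positive library above every single positive one. It was not called over all genes (limma adjusted p = 0.0706). B lymphocytes within the mCherry gate are a candidate source of the genes that fell, although that gate is meant to take macrophages, and ighm and cd37 reached means of 118 and 158 in single positive cells. The median log2 fold change of 17 B lineage genes, cd79a and cd22 among them, lay at -0.678 relative to that of all genes (-0.538 over a shorter list of 11 of them). That is between the bounds set for and against this source. Of the 17, 2 rose while 4 fell, of which PRDM1 alone held without any single library (others adjusted p up to 0.216). Of these genes cd79a and cd22 are also in the lymphocyte list, and SYK, LYN, BTK, PLCG2, cd40 and ciita are expressed by macrophages too. For more cells of every other type in the single positive gate, the prediction was a median within 1 of the lymphocyte list for each of 5 lists. Endothelial markers met it (gap 0.337). Cardiomyocyte, erythrocyte and thrombocyte, epicardial and fibroblast, and neutrophil markers lay 2.37, 2.852, 2.855 and 3.37 higher. Erythrocyte and thrombocyte (0.257), epicardial and fibroblast (0.261) and neutrophil medians (0.771) were above 0, so these lists were not higher in single positive cells. The explanation is not settled, because no gap passed the permutation test over genes. The adjusted permutation p was 0.156 for neutrophil markers and lowest, at 0.0566, for cardiomyocyte markers.

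Batch 1 alone called 0 genes (limma, 1364 at an unadjusted p under 0.05), and batch 2 alone called 412 higher and 152 lower. An effect of another direction in batch 1 is argued against for the 564 genes of batch 2, since 506 of them (89.7%) had the same sign in batch 1, but not for all genes, whose changes in the batches had a Pearson correlation of 0.311 across genes, nor for the mitochondrially encoded list (medians -0.74 and 0.75) or the extracellular matrix list (medians -2.03 and 2.45). A larger spread between the batch 1 libraries may account for part of it, because the double positive libraries of batch 1 differed by a median of 1.24 on the log2 scale and those of batch 2 by 0.781. Single positive libraries went the other way, with 0.817 in batch 1 and 0.996 in batch 2. Double positive library 1, in which 42.3% of genes lay under 1, was the farthest from the other libraries (median difference 1.36, others 1.05 to 1.21), and no biological explanation was tested.

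In 15 of 212 groups of 4 values (7.1%), 1 library lay far from the others, where chance gives about 1 in 20, and in 3 of these it was double positive library 1. Single positive library 1 had 11.8 normalized counts of cd9b (others 0.154 to 0.482), 35.9 of havcr1 (others 0.626 to 1.47), 1.55 of MOXD1 (others 0.0565 to 0.186) and 3.13 of TGFBI (others 0.104 to 0.105). Single positive library 4 had 92.7 of PAX5 (others 35.3 to 38.2) and 19.6 of MCOLN1 (others 66.0 to 84.0). Single positive library 5 had 716 of CANX (others 418 to 444). Double positive library 1 had 167 of MPEG1 ENSDARG00000055290 (others 394 to 452), 0.745 of CXCR4 ENSDARG00000057633 (others 0.250 to 0.261) and 738 of MT-ATP6 (others 1207 to 1282). Double positive library 4 had 2.14 of nppb (others 0.0580 to 0.178) and 1.52 of nlrc5 (others 0.102 to 0.230). Double positive library 5 had 252 of havcr1 (others 136 to 142), 230 of cd83 (others 382 to 407) and 13.2 of FEN1 (others 0.175 to 0.286).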

How the results depend on the processing

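The pseudocount of 0 was added after the data were seen, and its counts were 344 higher and 247 lower. No gene called between the populations changed sign under any alternative. Of the 23 gene lists, 12 passed camera's threshold, 11 to 14 did so under the other alternatives, and 0 with an estimated correlation. Batch 1 alone called 0 genes higher and 0 lower (limma, lowest adjusted p 0.0568), with 4 libraries in place of 8. There the extracellular matrix list had a median of -2.03 (camera adjusted p = 0.0595), reversed from 0.48 over both batches. The mitochondrially encoded list had one of -0.74 (camera adjusted p = 3.89e-07 at the preset correlation). It is counted as reversed by camera's direction alone. Over both batches its median was -0.03 and it was not called (camera adjusted p = 0.762). The cause was not tested for either list. The change of wt1b was 4.23 in batch 1 alone (adjusted p = 0.341), and 4.30 to 5.07 without single libraries. Batch 2 alone called 152 genes lower. Without single libraries the higher count ran from 169 to 497 and the lower count from 101 to 308. Without the mean-variance trend 124 genes were higher, and 41 named genes lost their call (adjusted p from 0.0553 to 0.357), and the cause was not tested. With the replicate block in place of the batch, 297 genes were higher and 176 lower. The same-numbered libraries had correlations of -0.191, -0.112, -0.292 and -0.192 between their deviations from the population means. No single positive library correlated best with its own number. An adjustment that equalises batch means would make the 2 populations of a batch deviate in opposite ways. These values therefore cannot tell whether libraries of equal number share hearts. All other alternatives left the counts within 1.5 times. For the named genes other than wt1b, 2062 alternative values kept their direction and side of the threshold, 208 fell short of it, 35 newly passed it and 0 reversed, and for lists 498 kept both, 19 fell short, 10 newly passed and 2 reversed. Besides wt1b, 75 named genes were past the threshold, and 56 of these were so without any single library. Read depth is unknown, so its limit on low values cannot be stated.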

Other observations

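The genes described here were chosen after their values were seen, from the 12 called genes of smallest p in each direction with a characterised symbol that the report does not select by rule, plus PRDM1. Double positive cells were higher in LRP1 ENSDARG00000029146, an endocytic receptor gene, which rose from 47.3 ± 36.4 to 1057 ± 478 normalized counts (SD, n = 4 each), a log2 fold change of 4.74 (SE 0.50, limma adjusted p = 9.14e-05). The dipeptidase gene CNDP2 rose from 43.3 ± 28.4 to 504 ± 119 and the fatty acid receptor gene GPR84 from 94.2 ± 52.4 to 690 ± 181 (SD, n = 4 each). Both amino acid transporter identifiers SLC43A2 ENSDARG00000061120 and SLC43A2 ENSDARG00000036848 rose, at log2 fold changes of 3.97 and 1.86, and the epoxide hydrolase gene EPHX2 rose by 3.07. The large scaffold gene ahnak was abundant in both populations, at 2153 ± 761 and 6818 ± 1128 (SD, n = 4 each). PRDM1, a transcription factor gene of plasma cells that macrophages also use, rose by 3.06 on the log2 scale (adjusted p = 0.000577), against the direction of ighm and PAX5. All genes named in this and the next paragraph stayed past the threshold without any single library.

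Among genes lower in double positive cells were the transcription factor genes FOS, BHLHE40 and NR1D1. FOS fell from 1937 ± 686 to 453 ± 182, BHLHE40 from 834 ± 188 to 206 ± 51.2 and NR1D1 from 444 ± 76.0 to 131 ± 14.3 (SD, n = 4 each). The log2 fold changes were -2.16, -2.02 and -1.74, with a limma adjusted p of 0.000280, 0.000256 and 0.000577. The myc family gene mych fell from 113 ± 38.2 to 3.28 ± 3.42 and the ependymin-like gene epdl1 from 666 ± 51.4 to 40.99 ± 33.1 (SD, n = 4 each). Another CXCR4 identifier, ENSDARG00000041959, fell by 1.58 (SE 0.28) from 548 ± 161 to 189 ± 81.7 (SD, n = 4 each), so that both CXCR4 identifiers were lower. Every double positive library lay below every single positive library for each of these 6 genes.

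The change between the populations differed between batches for 10 genes (limma interaction term, adjusted p under 0.05, 971 genes at an unadjusted p under 0.05). Among them, the log2 fold change in batches 1 and 2 was 1.53 and 4.77 for TIMP2 ENSDARG00000075261, 1.94 and 7.50 for c1qb, 3.05 and 6.43 for LRP1 ENSDARG00000029146, and -0.95 and 1.01 for MT-CO2. The 17 B lineage genes were also compared with the markers of 5 other cell types by permutation of genes, a test chosen after the values were seen. The lowest p was 0.0459, against endothelial markers (adjusted p = 0.229), with a difference of -1.42 between the median log2 fold changes. Across genes, which are not independent replicates, the log2 fold changes of the batches had a Pearson correlation of 0.311.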
